A study of Mus musculus with 4 samples.

How the data were processed

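Total RNA of sorted natural helper (NH), thymic DN2 and cultured lymphoid tissue inducer (LTi) cells was amplified by a two-cycle method, labelled with biotin and hybridized to Affymetrix mouse arrays, per the labels' protocols. The protocol attached to every sample describes mesentery digested with collagenase type I at 2 mg/ml with 4% albumin and passed through a 32 µm mesh, and was read as that of the NH cells. The authors deposited 1 table of intensity values on a linear scale for 45101 probe sets and 4 arrays. How probe intensities were summarized and scaled is not given in the sources used here, and detection calls were not used here. Groups came from the titles and source names: 2 NH arrays, 1 DN2 array and 1 LTi array.

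The array medians, 21.0, 18.9, 11.9 and 17.6, differed by up to 1.77 times. The limit set beforehand was 1.2, so quantile normalization was applied to log2(value + pseudocount), with the 25th percentile of all values, 4.62 intensity units, as the pseudocount. Quantile normalization gives every array the same distribution, so a global rise or fall of RNA cannot be seen, and the pseudocount shrinks differences of dim genes. Of the probe sets, 34958 carried 1 gene symbol in the platform annotation, 932 several and 9211 none there; 34754 of the first kind matched the reference gene table by gene number and no symbol changed. Each gene took its probe set with the highest mean over the arrays, which left 18194 genes, 7631 of those tested with over 1 probe set. The 12775 genes whose highest group mean reached the median of all values (17.1 intensity units) were tested.

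A mean per group was fitted with limma 3.58.1 in R 4.3.3 with a variance trend on intensity, and NH was compared with DN2 and with LTi. The fit had 1 residual degree of freedom, from the NH pair, and a prior of 5.31 degrees of freedom borrowed across genes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 difference of at least 1. LTi and DN2 were compared by size alone, at 4-fold. The number of arrays limits the precision. Tested on simulated data for NH against DN2 with 200 of 12775 genes changed, over 20 draws, the procedure recovered 4.6%, 39.4%, 75.8% and 93.0% of changes of 1, 2, 3 and 4 log2 units, with a mean of 14.1 false calls. The false calls were a larger share of all simulated calls than the threshold of 0.05 is set to allow. Many more genes, 4599, were called against DN2 in the data, so these rates need not hold there. The simulated arrays shared 1 variance per gene, so whether DN2 and LTi vary like NH was not checked. Depth on an array is signal over background: the floor of each array was its brightest of 27 probe sets for Bacillus subtilis genes (9.54, 13.5, 10.5 and 10.7 intensity units), a choice made after seeing the data. A group at or below the floor on each of its arrays has only a bound, and folds against it are lower bounds, taken from the floor.

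The text names, for NH against each control, the 12 called genes with the largest difference in each direction among genes with a descriptive symbol, the 10 per direction with the largest smaller difference against both controls, the 10 per direction by size for LTi against DN2, and members of 27 gene lists. The rule and the lists were written before the data were examined. The lists cover type 2 cytokines, cytokine receptors, group 2 innate lymphoid surface genes, T lineage, lymphoid tissue inducer, cytotoxic, transcription factor, chemokine receptor, eicosanoid, co-stimulatory, interferon, cell cycle, immediate early, MHC class II, glycolysis, lipid and gate genes. They also hold markers of stem cells, mast cells, adipocytes, fibroblasts, endothelium, macrophages, B cells, erythroid cells, hepatocytes and mesothelium. Of their 567 genes 474 were tested, and 40 had no probe set of their own alone and were not analysed here. A list median was placed among 10000 random lists of like size drawn from 10 bins of mean level, as a description of these arrays, and 35 of 54 medians against DN2 and LTi lay outside the central 95%. Member counts are given over all genes tested and adjusted over the list alone.

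Alternatives were other scalings, pseudocounts, filters, ways to combine probe sets, variance models, thresholds, and leaving out each NH array. Values as deposited, centring on 9 spike-in probe sets, a filter at 200 intensity units, and the called counts that still differed by at least 1 in 1 NH array were added after seeing the data. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.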

Results

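RNA levels were measured on 4 mouse arrays. Natural helper (NH) cells, innate lymphoid cells of the fat-associated lymphoid clusters, were sorted from the mesentery of C57BL/6 mice as lineage-negative cells with c-Kit and Sca-1 on their surface, and gave 2 arrays. The thymic DN2 cells, T cell progenitors sorted as CD25 and CD44 positive among CD4 and CD8 negative thymocytes, gave 1 array. The lymphoid tissue inducer (LTi) cells, innate lymphoid cells that initiate lymph nodes, gave 1 array. They had grown for 17 days on TSt4 stromal cells from fetal liver cells of day 13 embryos. The design used DN2 and LTi cells as the controls, so that NH cells could be set against an early T cell progenitor and against another innate lymphoid cell.

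Between 33.6% and 47.3% of the probe sets on an array lay at or below its noise floor, the brightest probe set for a bacterial gene. Across the 12775 genes tested, log2 levels correlated at 0.960 between the NH arrays, at 0.685 and 0.639 between them and DN2, and at 0.811 and 0.784 between them and LTi, with genes that are not independent replicates. The labels do not say whether the NH arrays came from separate animals. The p-values rest only on the spread between those NH arrays, moderated across genes, and need not cover the spread between animals. DN2 and LTi have no replicate, and their arrays were assumed to vary like those of NH cells. In what follows, differences are in log2 units with their standard error (SE), and a gene is called higher or lower at an adjusted p (limma) under 0.05 and a difference of at least 1. Folds are on the scale of intensity plus the pseudocount, and "at least" marks a fold against a group at the noise floor. A median "with bounds" has such genes at their bound.

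The first comparison asked how NH cells differ from DN2 thymocytes. NH cells held high levels of genes for type 2 cytokines and for receptors and regulators of group 2 innate lymphoid cells, and low levels of genes for receptor gene recombination, the pre-T cell receptor and the cell cycle. Of the genes tested, 2357 were called higher in NH cells and 2242 lower, 4599 in all, against 6380 at an unadjusted p under 0.05. Among the higher genes, both NH arrays lay at least 2-fold above DN2 for 2261, and among the lower genes both lay at least 2-fold below it for 2105. Genes of fibroblasts and endothelial cells were higher in the same arrays, with 20 of 22 and 13 of 14 called.

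Type 2 cytokines and other secreted effectors stood out, with 15 of 18 measured members higher than in DN2 over all genes tested, and 15 adjusted over the list alone. Their median difference was 5.26, or 3.89 with bounds. Csf2, which encodes the growth factor GM-CSF, was at least 274-fold higher (adjusted p = 7.2e-05), and Il6 at least 87.3-fold. Il13, at 6.29 and 7.70 in the NH arrays, was at least 6.51-fold higher. Il5, the growth factor of eosinophils, was at least 23.6-fold higher (adjusted p = 0.0036), with levels of 7.71 and 10.00 in the NH arrays. Il4, at 8.29 and 7.06, was at least 10.4-fold higher. Arg1, the enzyme that splits arginine, was at least 168-fold higher, and Cxcl2, a neutrophil chemokine, was at least 220-fold higher. Il9 and Il10 were not called.

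Among surface and signalling genes known from group 2 innate lymphoid cells, 20 of 32 were higher than in DN2 and 1 was lower, the same counts as when adjusted over the list alone, with a median of 2.51, or 2.50 with bounds. Gata3, the regulator of type 2 lymphocytes, differed by 3.09 ± 0.23 (adjusted p = 3.5e-04) and Rora, needed for group 2 innate lymphoid cells to develop, by 6.51 ± 0.25 (adjusted p = 7.2e-05). Klrg1, an inhibitory receptor, was 184-fold higher and the co-stimulatory receptor Icos 56.1-fold higher. Ccr8 and Ltb4r1, receptors for a chemokine and for leukotriene B4, were at least 21.9-fold and at least 57.3-fold higher. Il17rb, a chain of the interleukin 25 receptor, was the lower member at -1.17 ± 0.36 (adjusted p = 0.045), a call near its threshold that was lost with no filter or no variance trend. Of the cytokine receptor chains, 15 of 27 were higher and 3 lower, again the same adjusted over the list alone, with a median of 1.25. Il7r, the interleukin 7 receptor, differed by 1.45 ± 0.25.

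Among the genes of T lineage commitment and the pre-T cell receptor, 17 of 33 were lower in NH cells and 3 higher, and adjusted over the list alone these counts were 19 and 3. The list median was -1.19. Dntt, the enzyme that adds nucleotides at recombination joints, was at least 305-fold lower (adjusted p = 1.0e-04), Rag1 at least 20.1-fold lower and Ptcra at least 4.66-fold lower. Of the genes for the CD3 complex, Cd3g differed by -2.98 ± 0.30 and Cd3e by -3.17 ± 0.43. Bcl11b, which sets T lineage identity, was not called at -1.15 ± 0.39 (adjusted p = 0.06; -1.60 without NH array 1, -0.70 without array 2), and Gata3, Zap70 and Adam19 were the members that were higher. Lymphoid transcription factors went both ways, with 21 of 44 higher, 10 lower, a median of 0.83, and 21 and 13 adjusted over the list alone. Id2, which blocks E proteins, differed by 3.83 ± 0.15, and Myb, a factor of progenitor cells, was at least 210-fold lower. Bcl11a and Lyl1 were lower by at least 14.9-fold and 18.8-fold.

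Cell cycle genes were lower in NH cells in 34 of 38 cases, as they were adjusted over the list alone, with a median of -3.71, or -3.22 with bounds. Mki67, a marker of dividing cells, differed by -5.15 ± 0.30 and Top2a, a topoisomerase of S phase and mitosis, by -5.09 ± 0.29. Immediate early genes, which cells switch on within minutes of a stimulus, were higher in 33 of 40 cases (34 adjusted over the list alone) and lower in 1, with a median of 2.86, or 2.74 with bounds. Nr4a3 was 126-fold higher and Fosl2 81.1-fold higher, while Hspa8, a heat shock protein gene, was not called. The labels attach the same protocol of collagenase digestion to all 4 arrays, but it names only the mesentery, the tissue of the NH cells.

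The 12 called genes with the largest computed differences upward were Fabp4, Csf2, Dpt, Efemp1, Cxcl2, Igfbp7, Lmna, Fkbp9, Arg1, Abca8a, Cav1 and Lpl. All lay at or below the noise floor in DN2, so their order is not measured, and their lower bounds ran from 86.3-fold for Fkbp9 to 340-fold for Fabp4. Fabp4, a fatty acid carrier of adipocytes and endothelial cells, had an adjusted p of 7.2e-05. Dpt and Efemp1 encode matrix proteins of connective tissue, and Cav1 the coat protein of caveolae. The 12 with the largest differences downward were Myb, Dntt, Scin, Nfe2, Trbv13-2, Trat1, Myl10, Ly6d, Bex6, Ipcef1, Cdca5 and Arpp21. Arpp21, above the floor in both NH arrays, was 57.6-fold lower, and Scin lay at 2.95 and 4.54 in the NH arrays, below the floor in array 1, against 11.20 in DN2. Myb, Dntt, Nfe2, Bex6 and Ipcef1 were at the floor in NH cells, with bounds from at least 26.1-fold for Ipcef1 to at least 305-fold for Dntt, and Trbv13-2, Trat1, Myl10 and Cdca5 were below it in array 2 alone. Trbv13-2 is a T cell receptor variable gene, and Trat1 encodes an adaptor of the T cell receptor.

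The balance of calls depended on how the arrays were scaled. With quantile normalization 51.3% of the calls were higher in NH cells, with the values as deposited 69.5%, with arrays centred on spike-in probe sets 67.7% and with arrays centred on their medians 41.6%. The median tested gene differed by -0.20, 0.27, 0.24 and -0.38 in turn, and every difference is relative to that shift.

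**Figure D1:**
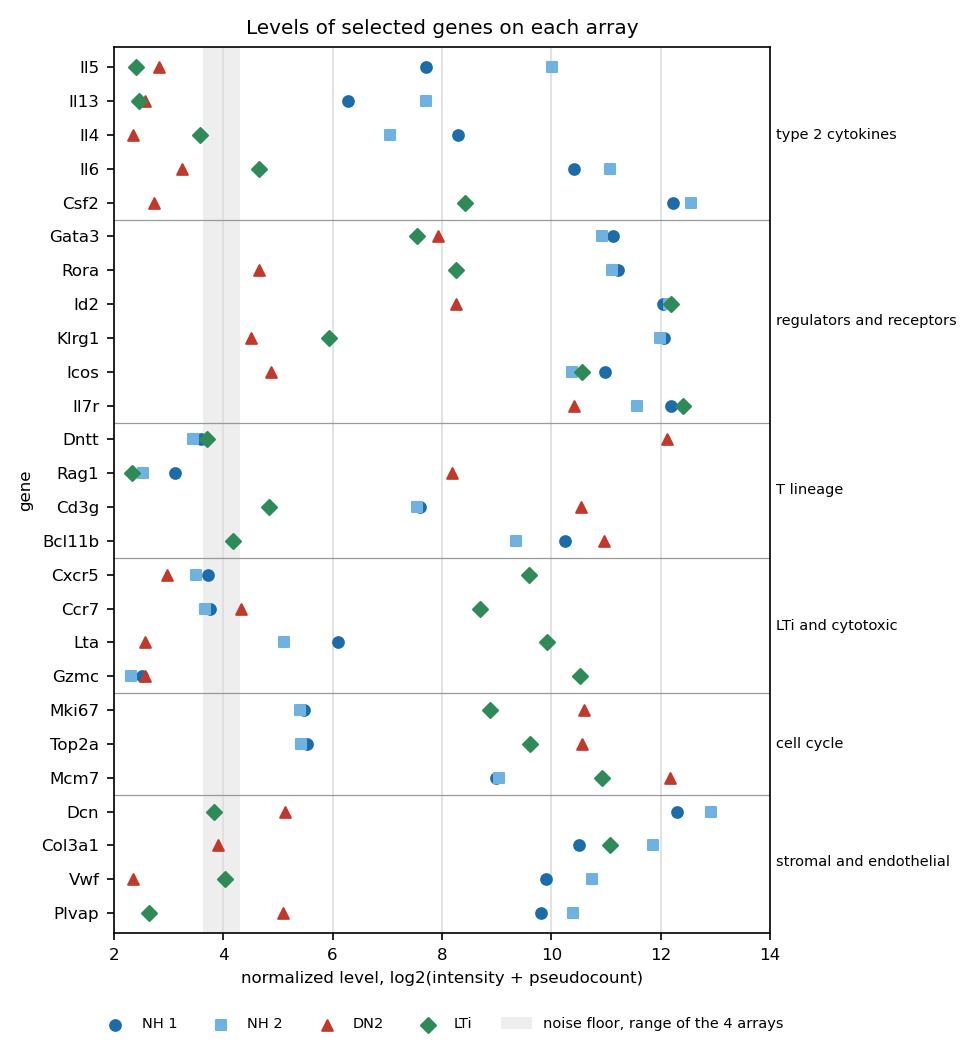
Normalized level of 26 genes on each array, as log2 of intensity plus the pseudocount on the horizontal axis, 1 symbol per array and the genes in rows by group, with the grey band spanning the noise floors of the 4 arrays (3.64 to 4.29). Gata3 lies at 11.13 and 10.92 in the NH arrays, 7.93 in DN2 and 7.54 in LTi, whereas Id2 lies at 12.04, 12.15, 8.26 and 12.18.

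The second comparison set NH cells against cultured LTi cells. NH cells were higher in type 2 cytokine genes and in several T lineage genes, and lower in some genes of lymphoid tissue inducer cells and in most of the listed genes of cytotoxic cells, the interferon response and the cell cycle. In all, 1123 genes were called higher in NH cells and 955 lower, 2078 together, against 4206 at an unadjusted p under 0.05. Both NH arrays differed at least 2-fold from LTi in the called direction for 1092 and 895 of them. Endothelial genes were higher in the NH arrays in 14 of 14 cases and macrophage genes lower in 8 of 23. RNA of any other cells in the LTi culture or in the sorted NH fraction was not separated out, which bears on every difference from LTi.

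Type 2 cytokines and secreted effectors were higher in 12 of 18 cases and lower in none, with 13 higher and 2 lower adjusted over the list alone. The median was 3.68, or 3.23 with bounds. Il5, at 7.71 and 10.00 in the NH arrays, was at least 30.5-fold higher, and Il13, at 6.29 and 7.70, at least 8.42-fold higher (adjusted p = 0.0075). Il6 differed by 6.09 ± 0.39. Csf2 was 15.7-fold higher, but lay at 8.42 in the LTi array, far above the floor. Lif, not called, was at 10.30 in LTi and at 9.20 and 8.12 in NH cells.

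Surface and signalling genes of group 2 innate lymphoid cells were higher in 18 of 32 cases and lower in 1, which held adjusted over the list alone, with a median of 1.87, or 1.02 with bounds. Klrg1 differed by 6.08 ± 0.25 (adjusted p = 3.7e-04), Gata3 by 3.49 ± 0.23, Rora by 2.90 ± 0.25 and Il17rb by 4.39 ± 0.36. Ccr9, a gut-homing receptor, was at least 45.1-fold higher and Ramp3, which modifies peptide hormone receptors, 83.5-fold higher. Icos, Il7r, Cxcr6 and Thy1 were not called. Cytokine receptor chains were higher in 5 of 27 cases and lower in 2, or 6 and 5 adjusted over the list alone (median 0.20, or 0.34 without NH array 2). The lower members were Il18r1 and Il18rap, the chains of the interleukin 18 receptor, at -4.17 ± 0.39 and -1.66 ± 0.32.

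Lymphoid tissue inducer genes were lower in 8 of 19 cases and higher in 2, with 10 and 2 adjusted over the list alone and a median of -1.50, and 9 were not called. Against DN2, 8 were higher and 2 lower, also adjusted over the list alone (median 1.09, or -0.08 with bounds). Cxcr5, the receptor that brings cells to follicles, lay at 9.60 in LTi and 3.72 and 3.50 in NH cells (adjusted p = 9.2e-04), and Ccr7 at 8.69 against 3.75 and 3.66, with NH array 2 below the floor for both. Lta, which encodes lymphotoxin alpha, differed by -4.31 ± 0.52. Id2 was not called, at 12.04 and 12.15 in NH cells and 12.18 in LTi. Genes of NK and other cytotoxic cells were lower in 13 of 23 cases and higher in none (15 lower adjusted over the list alone, median -2.02). Gzmc, a granzyme, was at least 102-fold lower and Klrd1, a chain of NK receptors, 48.2-fold lower. Interferon-stimulated genes were lower in 20 of 26 cases (22 adjusted over the list alone, median -1.88), such as Oasl2 at -3.48 ± 0.33 and Igtp at -2.48 ± 0.23. Against DN2 the NK list had 6 members higher and 5 lower (7 and 5 adjusted over the list alone, median 0.36, or -0.16 with bounds, 0.69 without NH array 1 and 0.08 without array 2), and the interferon list 2 and 4 (the same adjusted over the list alone, median -0.21, or -0.30 with bounds, -0.45 without NH array 1, 0.19 with the values as deposited and 0.16 with spike-in centring, so its sign depends on the scaling).

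T lineage genes were higher than in LTi in 13 of 33 cases and lower in 4, and no count changed when adjusted over the list alone (median 0.72, or 0.49 with bounds). Bcl11b differed by 5.63 ± 0.39 (adjusted p = 7.1e-04), Hes1, a target of Notch signalling, by 4.96 ± 0.25, Notch3 by 3.40 ± 0.34 and Cd3g by 2.74 ± 0.30. Lower members were Trat1, Cd28, Cd2 and Lef1. Cell cycle genes were lower in 31 of 38 cases, also adjusted over the list alone (median -2.59, or -2.12 with bounds), with Mki67 at -3.44 ± 0.30 and Top2a at -4.13 ± 0.29. Immediate early genes were higher in 29 of 40 cases, also adjusted over the list alone (median 2.48), and Nr4a3 differed by 6.36 ± 0.25. Transcription factors were higher in 10 and lower in 5 of 44 cases (14 and 6 adjusted over the list alone, median 0.29, or 0.16 without NH array 1), with Tox2 at -5.98 ± 0.33.

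The 12 called genes with the largest computed differences upward against LTi were Igkv8-30, Dcn, Igha, Inmt, Cxcl2, Dpt, Efemp1, Arg1, Plvap, Penk, Sox17 and Jchain. Cxcl2, Dpt and Arg1 were above the floor in LTi, at 207-fold, 199-fold and 182-fold, and the bounds of the others ran from at least 58.4-fold for Sox17 to at least 412-fold for Dcn. Igkv8-30, Igha and Jchain encode parts of secreted antibodies, Dcn a matrix proteoglycan and Plvap a protein of endothelial fenestrae. Sox17 is an endothelial transcription factor. The 12 with the largest differences downward were Gzmc, Cd7, Rspo2, Kng1, Cd160, Ipcef1, Kcnk1, Ddc, Hp, Bank1, Cxcr5 and Ifi202b. Gzmc, Cd7, Ipcef1, Kcnk1 and Ifi202b were at the floor in NH cells, with bounds from at least 27.1-fold for Ifi202b to at least 114-fold for Cd7, and Rspo2, Kng1, Cd160, Bank1 and Cxcr5 were below it in array 2 alone. Cd7 and Cd160 are surface receptors of lymphoid cells. The counts against LTi moved more with the model than those against DN2: with no trend of the variance on intensity, 738 genes were called higher and 462 lower.

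NH cells were then set against both controls. In all, 857 genes were called higher in NH cells than in both DN2 and LTi, and 491 lower. These counts were 521 and 218 with no filter, and 1243 and 485 with spike-in centring. With NH arrays simulated as unchanged against the controls, at most 3 and 5 genes were called so in 50 simulations, and independent lists would share 207 and 168. The log2 differences correlated at 0.561 across genes against a simulated 0.334, with a covariance of 1.32 against a simulated 0.0605. Both comparisons share the NH arrays, and so did the simulated ones, but there all 4 arrays had 1 common mean per gene. The simulation thus covers shared noise alone, and the independent lists do not cover sharing. How much overlap real differences give only because both comparisons share the NH arrays was not measured. In each NH array, 483 genes were at least 4-fold above both controls and 129 at least 4-fold below both, a rule of size with no test. Over the alternatives the first count ran from 292 (filter at 200 intensity units) to 686 (without NH array 1). The second ran from 75 (pseudocount at the 50th percentile) to 211 (without NH array 1). Leaving out an NH array could only raise these counts, since the rule then covers 1 array, and a stricter filter could only lower them. Of the called genes, 97 were higher than in DN2 and lower than in LTi, and 26 the reverse.

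The leading genes higher than in both were Cxcl2, Dpt, Efemp1, Arg1, Dcn, Sox17, Penk, Inmt, Sparcl1 and Abca8a. Cxcl2, Arg1 and Penk are on the list of type 2 cytokines and effectors, Dcn is on the fibroblast list, Dpt and Efemp1 encode matrix proteins of connective tissue, and Sox17 and Sparcl1 are known from endothelium. Fibroblast genes were higher than in DN2 in 20 of 22 cases and endothelial genes higher than in LTi in 14 of 14. From NH array 1 to array 2, Cxcl2 and Arg1 moved by -0.27 and -0.07, and the other 8 were higher in array 2 by between 0.55 for Sox17 and 1.18 for Penk, as were the fibroblast (1.11) and endothelial (0.65) medians. Cxcl2 was at least 220-fold above DN2 and 207-fold above LTi, and Abca8a at least 88.9-fold and 100-fold. Penk encodes the precursor of enkephalins, at 9.24 and 10.42 in NH cells against 2.70 in DN2 and 2.46 in LTi. The leading genes lower than in both were Ipcef1, Trat1, Nuf2, Kif22, Pbk, Cdca5, Fignl1, Pclaf, E2f8 and Kntc1. Nuf2, Kif22, Cdca5 and Kntc1 act at kinetochores or in chromosome segregation, and E2f8 is a cell cycle transcription factor. Ipcef1 was at least 26.1-fold below DN2 and at least 36.2-fold below LTi, and Kntc1 at least 21.4-fold and at least 11.2-fold.

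**Figure D2:**
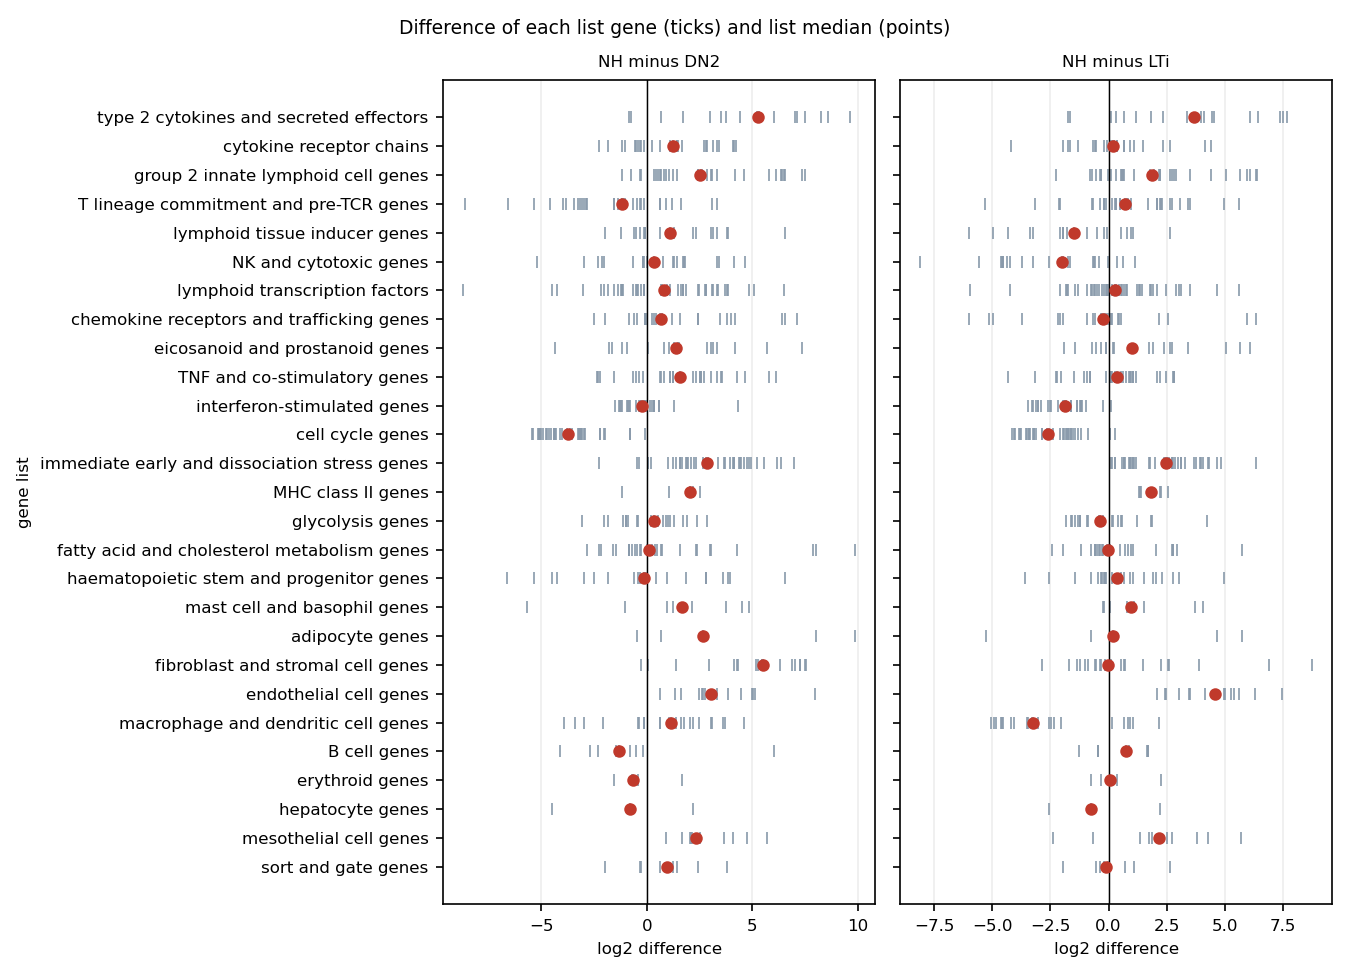
Log2 difference on the horizontal axis of each measured gene (grey ticks) of 27 gene lists, with the list medians as red points, for NH minus DN2 on the left and NH minus LTi on the right. Cell cycle genes have medians of -3.71 and -2.59, type 2 cytokines and secreted effectors 5.26 and 3.68, and fibroblast genes 5.49 and -0.01.

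Markers of several cell types other than lymphocytes were also high in the NH arrays. Genes of fibroblasts and stromal cells were higher than in DN2 in 20 of 22 cases, also adjusted over the list alone (median 5.49, or 5.08 with bounds). Against LTi, 6 were higher and 1 lower, or 6 and 3 adjusted over the list alone (median -0.01). The LTi median was 0.55 without NH array 1 and -0.42 without array 2, so its sign rests on 1 array. Dcn lay at 12.30 and 12.92 in the NH arrays, 5.13 in DN2 and 3.84 in LTi. Col3a1, a fibrillar collagen, lay at 10.51 and 11.87 against 3.91 and 11.07. Endothelial genes were higher than in DN2 in 13 of 14 cases (median 3.06, or 2.87 with bounds) and than in LTi in all 14 (median 4.56, or 3.56 with bounds), also adjusted over the list alone. Vwf, the clotting factor carrier of endothelium, was at least 65.2-fold above DN2 and 78.0-fold above LTi. Mesothelial genes were higher in 9 of 10 cases against DN2 (median 2.32, or 1.82 with bounds) and in 6 against LTi (median 2.19, or 1.81 with bounds). Adjusted over the list alone, 9 were higher against DN2, and 7 higher and 1 lower against LTi.

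Other marker lists were mixed. Over all 12775 genes tested, 2357 were called higher and 2242 lower than in DN2, shares close to those of the macrophage list. Macrophage, monocyte and dendritic cell genes were higher than in DN2 in 5 of 23 cases and lower in 4, also adjusted over the list alone, with a median of 1.17, or 0.63 with bounds. That median was -0.10 without NH array 1 and 2.07 without NH array 2, so 1 array sets its sign. Against LTi, 8 were lower, or 15 adjusted over the list alone (median -3.26, -4.50 without NH array 1 and -1.75 without array 2), and Cd68 lay at 6.71 and 5.27 against 9.29. MHC class II genes were higher than in DN2 in 4 of 6 cases and lower in 1, also adjusted over the list alone (median 2.03). Against LTi 1 was higher, or 5 adjusted over the list alone (median 1.83). Mast cell and basophil genes were higher than in DN2 in 5 of 8 cases and lower in 1 (median 1.69, or 1.12 with bounds, the same counts adjusted over the list alone), and than in LTi in 3 (4 adjusted over the list alone, median 0.95). Hdc, the histamine-forming enzyme, was called higher than in both controls and was 17.0-fold above LTi, whereas Cpa3, a mast cell protease, was 51.0-fold lower than in DN2. Genes of stem and progenitor cells were higher in 7 and lower in 6 of 22 cases against DN2, also adjusted over the list alone (median -0.14, -0.04 without NH array 1 and -0.21 without array 2). Against LTi they were higher in 6 and lower in 2 (8 and 2 adjusted over the list alone, median 0.35, or 0.02 with bounds, 0.57 without NH array 1 and -0.02 without array 2).

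Adipocyte genes were higher in 3 of 5 cases against DN2 (median 2.68), and higher in 2 and lower in 1 against LTi (median 0.20, 0.0048 without NH array 1 and 0.39 without array 2). Adipoq, the adipocyte hormone adiponectin, was the lower member at -5.28 ± 0.41. B cell genes were higher in 1 and lower in 3 of 9 cases against DN2 (median -1.32) and none was called against LTi (median 0.74, or -0.43 with bounds, 0.27 without NH array 1). Erythroid genes gave 1 higher and 1 lower of 5 against DN2 (median -0.63) and 0 against LTi (median 0.07, or 0.06 with bounds, 0.17 without NH array 1 and -0.04 without array 2), and hepatocyte genes 1 and 1 of 3 against each control (median -0.77 against both). Each of these counts was the same adjusted over the list alone.

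Genes behind the sorting gates were set beside the labels. Kit was higher in NH cells than in DN2 (1.25 ± 0.27) and LTi (1.10 ± 0.27), and Thy1 was not called against either. Il2ra, which encodes CD25, lay at 10.00 in DN2, 10.00 and 9.35 in NH cells and 7.03 in LTi. Itga4 was lower than in both, by 3.99-fold and 3.92-fold, and Itgb7 differed by 3.81 ± 0.18 from DN2. Of the 8 measured gate genes, 4 were higher and 1 lower against DN2 (median 0.94), and 2 and 1 against LTi (median -0.11, -0.23 without NH array 1 and -0.0011 without array 2), the same adjusted over the list alone. Chemokine receptors and trafficking genes were higher in 11 and lower in 2 of 24 cases against DN2 (median 0.68, or 0.50 with bounds), and 4 and 7 against LTi (median -0.25), again the same adjusted over the list alone. Ccr2, a receptor for monocyte chemokines, was at least 107-fold above DN2 and was not called against LTi.

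The third comparison, LTi against DN2, rests on 1 array each and has no replicate check and no test. By size, 1098 genes were at least 4-fold higher in LTi and 510 at least 4-fold lower. The LTi array held Il18r1 (at least 104-fold higher), the chemokine Cxcl12 (at least 242-fold) and Lgals3 (at least 206-fold), along with Lpl, Pcolce, Igfbp7, Col1a2, Kng1, Fkbp9 and Hp. DN2 cells held Dntt (at least 292-fold lower in LTi), Dpp4 (at least 65.5-fold) and Bcl11b (110-fold), along with Scin, Myl10, Ly6d, Trbv13-2, Myb, Arpp21 and Bex6. Of the 19 lymphoid tissue inducer genes, 13 were at least 4-fold higher in LTi (median 3.28, or 2.70 with bounds), and of 33 T lineage genes 20 were at least 4-fold lower (median -2.96, or -2.16 with bounds). NK and cytotoxic genes had a median of 3.81, or 2.70 with bounds, interferon-stimulated genes 1.71 and cell cycle genes -1.24. Macrophage genes had a median of 4.12, or 3.78 with bounds, and fibroblast genes 4.23, or 3.50 with bounds, with Csf1r, the receptor of macrophage growth factor, at 11.34 in LTi and 5.21 in DN2. The LTi cells had grown on TSt4 stromal cells, and RNA of LTi cells cannot be told apart here from RNA of other cells in the culture. The count of lower genes was 326 with the values as deposited, 191 with the filter at 200 intensity units and 750 with the pseudocount at the 5th percentile. For higher genes it was 573 with the filter at 200 intensity units and 1460 with the values as deposited.

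The NH arrays differed from one another in marked groups of genes. Their difference had an SD of 0.603 over genes, and 1118 genes (8.75%) lay at least 2-fold apart. Fibroblast genes were higher in array 2 in 21 of 22 cases (median 1.11), endothelial genes in 13 of 14 (0.65) and mesothelial genes in 9 of 10 (0.60). Macrophage genes were higher in array 2 in 2 of 23 cases (-1.56), and MHC class II genes in 0 of 6 (-1.31). Sort and gate genes were higher in array 2 in 2 of 8 cases (-0.38), NK and cytotoxic genes in 17 of 23 (0.35) and fatty acid and cholesterol genes in 22 of 28 (0.28). All of these medians lay outside the central 95% of random lists, and the other 19 lists lay inside it, among them the group 2 innate lymphoid list (-0.12) and the cell cycle list (-0.08). C1qb, a complement gene of macrophages, lay at 8.18 in array 1 and 4.27 in array 2.

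**Figure D3:**
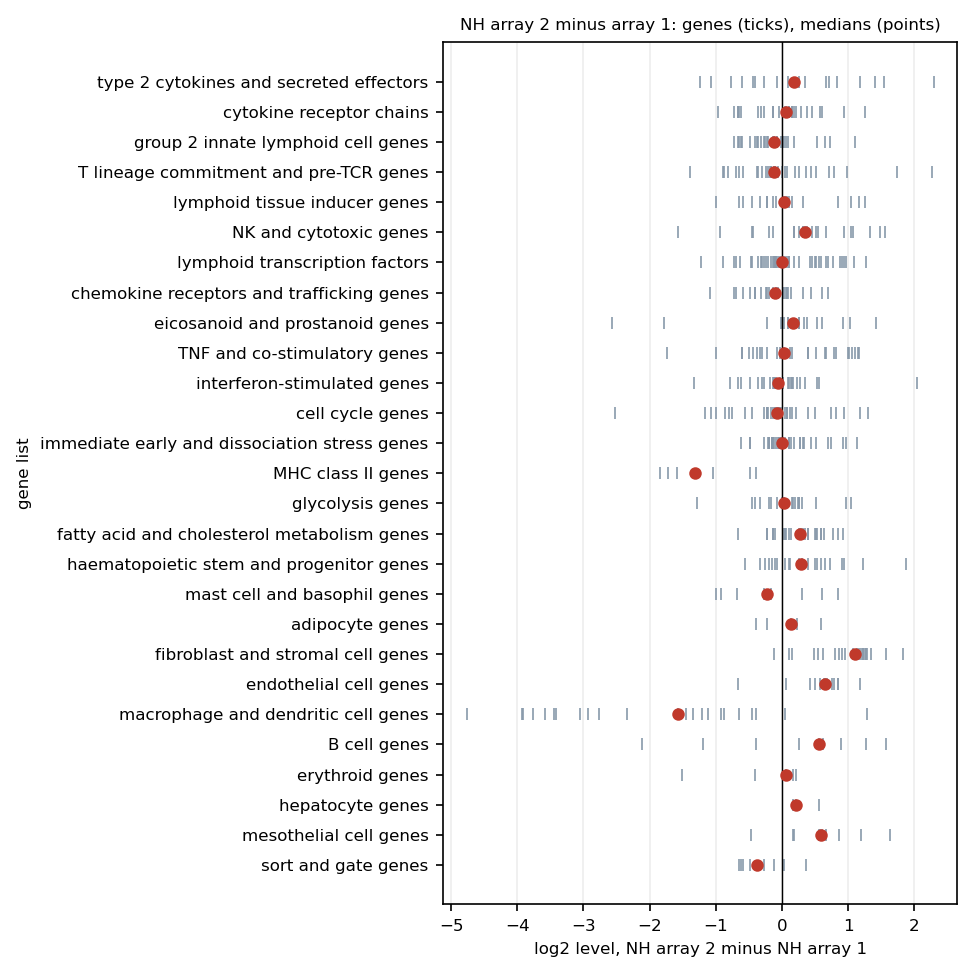
Log2 level in NH array 2 minus array 1 on the horizontal axis for each measured gene (grey ticks) of 27 gene lists, with red points at the list medians. Fibroblast genes sit to the right with a median of 1.11, macrophage genes to the left with -1.56, and group 2 innate lymphoid genes near 0 with -0.12.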

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

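All tests of explanations in this part were chosen after the patterns were seen. Probe sets with several gene symbols or none took no part in the comparisons. Of 4617 such probe sets above the filter, 125 were at least 4-fold higher in each NH array than in DN2 and LTi (2.71%, against 3.78% of named genes), and 23 were at least 4-fold lower; no biological explanation was tested.

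Fibroblast, endothelial and mesothelial genes were higher in the NH arrays than in DN2, with Dcn at 12.30 and 12.92. Scaling between arrays as the whole cause is argued against by the fibroblast median against DN2, which was 5.30 at its lowest over 4 scalings. A candidate explanation is RNA of such cells in the sorted fraction: the fibroblast median rose by 1.11 from NH array 1 to array 2, the endothelial and mesothelial medians moved the same way, while the group 2 innate lymphoid list moved by -0.12, the sort and gate list by -0.38 and the macrophage list by -1.56. How far the lineage-negative, c-Kit and Sca-1 positive gate removed such cells is not known, since its lineage markers are not given in the sources used here. Of the 22 fibroblast genes 1, and of the 14 endothelial genes 1, is on another list too. Of the 36 group 2 innate lymphoid genes 28 are, as are all 10 gate genes. The group 2 and gate lists share members, so their shifts are not separate observations. Expression of these genes by NH cells themselves stays open and was not tested.

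Immediate early genes were high in the NH arrays, with 33 of 40 called higher than in DN2. Digestion of the tissue and isolation of the cells cannot be told apart from the cell type, since the digestion protocol, attached to all 4 arrays, names only the tissue of the NH cells. Fibroblast and endothelial RNA as the whole source is argued against by the shift from NH array 1 to array 2, whose upper quartile over the 40 genes was 0.27 (median 0.00), below the lower quartiles of the fibroblast (0.67) and endothelial (0.52) lists. For the 15 dimmer members, below 11 log2 units, it stays open, since their upper quartile was 0.72 (median 0.11). The result over the 40 genes thus rests on the brighter members, and the lists compared were not matched on level. A mix with RNA of macrophages, whose genes moved the other way (-1.56), is not covered by this test. A more active state of NH cells in the animal may also account for the pattern and was not tested.

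Cell cycle genes were low in the NH arrays. Scaling as the whole cause is argued against by the median against LTi, which stayed at -2.48 or below over 4 scalings. Dilution by RNA of other cells as the whole cause would lower the gate genes about as much, if both cell types held them alike. Their lower quartile against LTi was -0.40, while the upper quartile of the cell cycle genes was -1.64. These values cannot decide the question, since c-Kit was a gate of the NH sort and Thy1 is also on the fibroblast list. The LTi array held RNA of fibroblast genes too, with a median NH difference of -0.01. A lower rate of division in NH cells than in DN2 cells or in LTi cells in culture may account for the pattern as a hypothesis, found and examined on the same arrays.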

How the results depend on the processing

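Alternatives other than the values as deposited, the spike-in centring, the filter at 200 intensity units and the called counts without an NH array were fixed before the data were examined. No paired analysis was possible because only the NH cells have 2 arrays. Counts within 1.5 times of the reported one are left out below. The cause was not tested, apart from changes that follow from the number of genes or arrays that entered. With no filter, 638 genes were called higher and 434 lower than in LTi, 521 higher and 218 lower than in both controls, and 2076 genes lay 2-fold apart between the NH arrays. Without a variance trend, 738 were higher and 462 lower than in LTi, and 222 lower than in both. With the filter at 200 intensity units, which tested 5782 genes, 1323 were higher and 1364 lower than in DN2, 725 higher than in LTi, and by size 292 were above both controls, 573 higher and 191 lower in LTi than in DN2, and 282 apart between the NH arrays. With the pseudocount at the 50th percentile, 75 genes were 4-fold below both controls, 260 lower in LTi than in DN2 and 503 apart between NH arrays. Averaging probe sets gave 82 genes below both. Without 1 NH array, between 189 and 211 were below both, a count that could only rise since the rule then covers 1 array. Genes lower in LTi than in DN2 numbered 308 with the filter at the 75th percentile, 321 with the filter on the mean and 326 with the values as deposited. Genes apart between NH arrays numbered 489 and 718 under those filters and 1785 over every probe set.

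With every probe set tested by itself, the Lmna probe set with the lowest difference from LTi gave -0.0716, the reverse of the 1.62 ± 0.34 of the probe set used, and the cause was not tested. The Il17rb call against DN2 was lost with no filter, no variance trend, the pseudocount at the 50th percentile and the values as deposited. Other calls of genes checked for this text moved too. With every probe set by itself 169 called differences stayed and 19 weakened. With no variance trend 13 weakened, with no filter 12 and with probe sets averaged 5. Among differences not called, 12 became stronger with the values as deposited and 11 with spike-in centring. List medians that changed sign against DN2 were fatty acid genes (-0.28 with the filter at the 75th percentile, -0.12 with probe sets averaged, -0.05 with arrays centred on their medians), stem and progenitor genes (0.19 with that filter, 0.14 with probe sets averaged, 0.43 with the filter on the mean, 0.30 as deposited, 0.27 with spike-in centring), glycolysis genes (-0.01 with arrays centred on their medians), interferon-stimulated genes (0.19 as deposited, 0.16 with spike-in centring) and macrophage genes (-0.10 without NH array 1). Against LTi they were adipocyte genes (-0.03 with no filter, -0.20 with probe sets averaged), hepatocyte genes (0.06 with no filter), fibroblast genes (0.18 with probe sets averaged, 0.55 without NH array 1, 0.05 as deposited, 0.07 with spike-in centring), fatty acid genes (0.09 without NH array 1, 0.04 as deposited, 0.06 with spike-in centring), stem and progenitor genes (-0.02 without NH array 2) and erythroid genes (-0.04 without NH array 2, -0.19 as deposited, -0.18 with spike-in centring).

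Outside the central 95% of random lists lay between 34 and 38 list medians in the alternatives, against 35 of 54, with fewer lists measured under the filters at the 75th percentile and on the mean. What signal over background limits is shown by the floor: 33.6% to 47.3% of the probe sets on an array gave no level above it.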

Other observations

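Some genes of eicosanoid and prostanoid signalling were higher in NH cells. Against DN2, 8 of 18 were higher, 3 lower and 7 not called, with 10 and 3 adjusted over the list alone (median 1.38, or 1.05 with bounds). Against LTi 8 were higher, none lower and 10 not called, with 9 higher adjusted over the list alone (median 0.99, or 0.96 with bounds). Alox5, the first enzyme of leukotriene synthesis, was 52.5-fold above DN2 and 67.0-fold above LTi. Ltb4r1, the leukotriene B4 receptor, was at least 57.3-fold and 50.8-fold above them, Ptgir, the prostacyclin receptor, 18.3-fold and 33.2-fold, and Ptger3 8.78-fold and 10.8-fold. Alox5ap, the partner of Alox5, was lower than in DN2 (-4.33 ± 0.93), but lay at 7.71 and 5.14 in the NH arrays. Genes of the tumour necrosis factor and co-stimulatory families were higher than in DN2 in 18 of 31 cases and lower in 4, also adjusted over the list alone (median 1.57, or 1.25 with bounds). Against LTi, 7 were higher and 4 lower, or 7 and 5 adjusted over the list alone (median 0.38). Tnfrsf25 was at least 21.4-fold and Pdcd1lg2 at least 16.5-fold above DN2.

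Lipid and sugar metabolism showed single genes, not a common shift. Fatty acid and cholesterol genes were higher than in DN2 in 9 and lower in 5 of 28 cases (median 0.13, or 0.06 without NH array 2), and 7 and 3 against LTi (median -0.03, 0.09 without NH array 1 and -0.06 without array 2), the same adjusted over the list alone. Dgat1, the last enzyme of triglyceride synthesis, was 19.6-fold above DN2 and 7.68-fold above LTi, and Pparg, a nuclear receptor of lipid storage, 8.34-fold and 6.64-fold. Glycolysis genes were higher in 6 and lower in 5 of 21 cases against DN2 (median 0.36, or 0.19 with bounds, or 0.23 without NH array 2, the same adjusted over the list alone), and 4 and 4 against LTi (4 and 7 adjusted over the list alone, median -0.35). With arrays centred on their medians, the medians against DN2 turned to -0.05 for the lipid list and -0.01 for glycolysis. Slc2a3, a glucose carrier, was 7.33-fold above DN2 and 18.9-fold above LTi.

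Some immunoglobulin genes, looked at after their values were seen, were higher in the NH arrays than in the controls. Of 15 tested, 9 were higher than in DN2, 8 higher than in LTi and 6 higher than in both, and none was called lower. All 15 lay higher in NH array 2 than in array 1, by a median of 1.75. Igha lay at 11.63 and 12.82, with 6.79 in DN2 and 3.77 in LTi. Whether NH cells or other cells in the sorted fraction held this RNA was not tested.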
